A study of Arabidopsis thaliana with 189 samples.

How the data were processed

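The deposited files held estimated counts and TPM, the length-scaled abundance of Salmon, for 33681 genes, made before deposition with fastp 0.20.0, Salmon 1.0.0 and the TAIR10 genome as the authors' notes name them. The notes do not say which step each tool did. In the 13023 genes checked, the deposited estimated counts equalled TPM times a factor per gene and a factor per library, so for these both files hold the same measurement. The other genes were not checked. The counts may therefore be length-scaled estimates rather than direct Salmon counts, which the notes leave open and which bears on the count model. All columns were used. Genes were matched to the TAIR10.1 gene names, 32954 of them by identifier, and 10613 carried a symbol. The chromosome of a gene is the digit after AT in its identifier. Reads were not analysed here. Total counts of a library ran from 13872623 to 28000033 with a median of 19128584. The chi-square per degree of freedom between replicate pairs ran from 3.04 to 133.97 with a median of 9.44.

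Counts were rounded and fitted with edgeR 4.0.16 quasi-likelihood in R 4.3.3, with a coefficient per day and genotype, TMM scaling and the edgeR low-count filter by group (minimum count 10, minimum total 15). Shoots, leaves and the tissue comparison were fitted separately, which tested 20802, 20743 and 20363 genes. Contrasts averaged the days of a period with equal weight, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. The mid-parent was the arithmetic mean of the fitted parental levels of a day, entered as an offset of the F1 libraries. A gene lay outside the parental range when F1 differed from both parents in the same direction, with the larger p of both tests and the smaller fold. Interactions compared the parental difference, or the F1 deviation, between the late and the early period. The position of F1 was (F1 - Col-0)/(Per-1 - Col-0) on CPM for genes with parents at least 2-fold apart. The design, the gene lists and the alternatives were written before the data were examined.

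The 21 gene lists held 440 genes, of which 434 were used. They covered the light reactions, the Calvin cycle, chlorophyll synthesis, mitosis and cytokinesis, DNA replication, the cytosolic ribosome, auxin and shade growth, salicylic acid defence, the clock, senescence, aliphatic glucosinolates, anthocyanin, cell wall loosening, starch, seed reserves, flowering, heat shock, wounding and touch, the shoot meristem, root markers and the stomatal lineage. Lists were tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2, and the difference of a list is the mean over its genes. The age interactions were tested for 5 lists. The list tests of the tissue comparison were added later. The camera test of limma was used as an alternative with a preset correlation of 0.01 and with an estimated correlation between genes. Camera asks whether a list changed more than the other genes, whereas fry asks whether the genes of the list changed at all. Adjusted p-values given with a preset or an estimated correlation are from camera, so they also answer another question.

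Genes were named by a rule. These were the 2 largest rises and falls of a comparison with a mean of at least 10 CPM and the same direction on each day, up to 4 genes of a list that passed, and a fixed set of clock, division, photosynthesis, defence and flowering genes. Not all genes that the rule picked are in the text. Near-identical copies were sought by shared words of 31 bases.

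Alternatives were DESeq2 1.42.0, limma on log2(TPM + 1), RLE scaling, no or a stricter low-count filter, a geometric mid-parent, a minimum fold of 1.5, fits of only the days compared, and fits without each replicate number or with it as a block. For lists they were log2(TPM + 1) and members of at least 1 CPM, and for the position a 4-fold minimum. Chance was measured by 100 splits of the libraries, the real one included. On simulated data made from the shoot counts, the edgeR fit found 76% of genes changed 1.25-fold, 88% at 1.5-fold and 100% at 2-fold between the parents, with 8 false calls in 20002 unchanged genes. At 1.25-fold it found fewer for the change of the parental difference with age, 44% in shoots and 54% in leaves. For F1 outside the parents it found 56% and 50% at 1.25-fold in shoots of 3 to 5 and 6 to 8 DAS. False calls of edgeR reached 19 in another shoot comparison and 25 of 19943 in leaves. With F1 at the mid-parent of parents 4-fold apart, 0 of 50 genes were called. The changed genes were drawn from those with a mean count of at least 50, so lower counts were not tested. For each kind of contrast 200 genes changed, as many up as down. In the real shoots of 3 to 5 DAS 12369 of 20802 genes were called between the parents. False calls and scaling under such widespread change were therefore not tested. The fry test called 20 of 20 lists changed 1.25-fold and 0 of 20 unchanged lists in shoots, and 20 of 20 and 1 of 20 in leaves. These lists held random genes simulated independently, with all members changed alike. The rates therefore do not carry over to the real lists, whose genes can vary together. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15, with NumPy 2.4.6 and pandas 2.3.3.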

Results

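RNA was sequenced from Arabidopsis seedling shoots collected daily from 3 to 8 days after sowing (DAS) and from the first true leaf collected daily from 7 to 21 DAS. The plants were the ecotypes Col-0 and Per-1 and their F1 hybrid. Each of the 63 combinations of tissue, day and genotype had 3 libraries, which made 54 shoot libraries and a larger leaf set. The ranges of total counts of the genotypes overlapped in both tissues. Days were pooled into 5 periods. A genotype had n = 9 libraries in shoots of 3 to 5 DAS and of 6 to 8 DAS, and n = 12, 15 and 18 in leaves of 7 to 10, 11 to 15 and 16 to 21 DAS. Levels are TMM-scaled CPM, given as the mean ± SD between libraries of a day. Differences are log2 values ± SE that average the days with equal weight, so they can depart from the ratio of the mean CPM. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure a spread between libraries that may be technical.

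The comparison of Per-1 with Col-0 asked how the parents of the hybrid differed at the same age, with cell division and photosynthesis, the capacities named in the series title, in view. In shoots of 3 to 5 DAS, photosynthesis genes were higher and mitosis genes lower in Per-1, though none of these lists passed with an estimated correlation. LHCA1 (AT3G54890), an antenna protein of photosystem I, had 3130 ± 330 CPM in Col-0 and 4650 ± 290 in Per-1 (SD, n = 9), a log2 difference of 0.61 ± 0.06. TES (AT3G43210), a kinesin of cytokinesis, had 10.3 ± 0.76 CPM in Col-0 and 4.21 ± 0.41 in Per-1, a difference of -1.30 ± 0.09. The edgeR adjusted p-values were 2.3e-11 and 1.1e-16. The Col-0 shoots in this comparison held root transcripts: the root hair gene PRP3 (AT3G62680) stood at 112 ± 27 CPM in Col-0 and 4.99 ± 3.5 in Per-1 at 3 DAS, and at 11.6 ± 4.2 and 0.553 ± 0.27 at 4 DAS (n = 3). At 6 DAS it stood at 0.019 ± 0.033 in Col-0 and 3.02 ± 0.79 in Per-1, and the root list was higher in Per-1 by 1.38 ± 0.17 at 6 to 8 DAS. Root tissue was not excluded as a part of the differences between the shoots of either period.

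Of 40 measured genes for the light reactions of photosynthesis, 38 were higher and 0 lower in Per-1 shoots of 3 to 5 DAS, and 38 passed when adjusted over the list alone. The mean difference was 0.38 ± 0.05 (adjusted p = 4.5e-08, and adjusted p = 0.91 with an estimated correlation), and 0.27 without the shoots of 3 DAS (adjusted p = 1e-04). At 6 to 8 DAS 24 were higher and 1 lower, and 26 passed when adjusted over the list alone. The mean was 0.17 ± 0.05 (adjusted p = 0.0046, or 0.91 with an estimated correlation). In leaves of 7 to 10 DAS 20 were higher and 2 lower at a mean of 0.10 ± 0.04 (adjusted p = 0.025, or 0.91 with an estimated correlation), and without the leaves of 7 and 8 DAS the adjusted p was 0.085. FNR2 (AT1G20020), which passes electrons to NADP, rose from 546 ± 32 CPM in Col-0 to 777 ± 40 in Per-1 there (0.51 ± 0.04, n = 12). In leaves of 11 to 15 DAS 4 were higher and 15 lower, and the mean of -0.05 ± 0.04 (adjusted p = 0.28) turned to 0.006 on log2(TPM + 1). The mean at 16 to 21 DAS was 0.06 ± 0.03 (adjusted p = 0.088), with 15 genes higher and 7 lower. Plastocyanin PETE1 (AT1G76100) had 204 ± 21 CPM in Col-0 and 399 ± 29 in Per-1 there (0.96 ± 0.04, n = 18).

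Genes of the Calvin cycle were higher in Per-1 in the youngest shoots and lower in leaves of 11 to 15 and 16 to 21 DAS. In Per-1 shoots of 3 to 5 DAS 18 of 19 were higher, 18 when adjusted over the list alone, by 0.33 ± 0.05 (adjusted p = 1.7e-07, or 0.91 with an estimated correlation). The mean was 0.21 without the shoots of 3 DAS (adjusted p = 0.0014). GAPB (AT1G42970), of the glyceraldehyde phosphate dehydrogenase, had 2570 ± 230 CPM in Col-0 and 3510 ± 170 in Per-1 (0.51 ± 0.05, n = 9). In shoots of 6 to 8 DAS and leaves of 7 to 10 DAS they did not pass, at 0.11 ± 0.05 and 0.07 ± 0.04 (adjusted p = 0.051 and 0.091). The latter was -0.05 without the leaves of 7 and 8 DAS (adjusted p = 0.38). In leaves of 11 to 15 DAS 16 were lower and 1 higher, 17 when adjusted over the list alone, by -0.19 ± 0.03 (adjusted p = 2.4e-07, or 0.91 with an estimated correlation). GAPA (AT3G26650), its partner subunit, had 4970 ± 310 and 3740 ± 200 CPM (-0.41 ± 0.04, n = 15). At 16 to 21 DAS 13 were lower and 0 higher at a mean of -0.14 ± 0.03 (adjusted p = 8.5e-06, or 0.91 with an estimated correlation). The chlorophyll synthesis list rose in Per-1 at 16 to 21 DAS by 0.32 ± 0.03 (adjusted p = 3.3e-12, or 0.91 with an estimated correlation), with 10 of 19 genes higher, 4 lower and 14 passing when adjusted over the list alone. Its protochlorophyllide reductase PORB (AT4G27440) had 36.7 ± 18 CPM in Col-0 and 221 ± 43 in Per-1 (2.60 ± 0.12, n = 18).

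In each period more mitosis genes were lower than higher in Per-1, but the list tests given below did not pass with an estimated correlation. Of 28 genes, 23, 21, 20, 16 and 9 were lower from the youngest shoots to the oldest leaves and 2, 2, 2, 2 and 3 higher, with 25, 24, 22, 18 and 12 passing when adjusted over the list alone. The mean was -0.32 ± 0.05 in shoots of 3 to 5 DAS (adjusted p = 3.8e-07), -0.21 ± 0.07 in leaves of 7 to 10 DAS (adjusted p = 0.0046) and -0.25 ± 0.06 in leaves of 16 to 21 DAS (adjusted p = 0.0024), each with an adjusted p = 0.91 with an estimated correlation. The mean of the youngest shoots was -0.26 without those of 3 DAS (adjusted p = 0.00056), and that of leaves of 7 to 10 DAS was -0.33 without the days 7 and 8 (adjusted p = 0.0039). DNA replication genes were lower in Per-1 leaves: 24, 21 and 20 of 25 fell in the 3 leaf periods, 0, 0 and 1 rose, and 24, 22 and 22 passed when adjusted over the list alone. The means were -0.33 ± 0.05, -0.41 ± 0.05 and -0.47 ± 0.04 (adjusted p = 3.1e-08, 1.1e-12 and 8.6e-17, and 0.91 with an estimated correlation in each). RNR1 (AT2G21790), the large subunit of ribonucleotide reductase, had 178 ± 5.8 CPM in Col-0 and 113 ± 7.7 in Per-1 leaves of 7 to 10 DAS (-0.67 ± 0.06, n = 12). In shoots of 3 to 5 DAS the DNA replication mean was -0.07 ± 0.03 (adjusted p = 0.022, or 0.91 with an estimated correlation), and -0.04 without the shoots of 3 DAS (adjusted p = 0.19).

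Flavonoid and defence genes also differed between the parents. All 17 measured anthocyanin synthesis genes were lower in Per-1 leaves of 7 to 10 DAS, 17 when adjusted over the list alone, by -2.26 ± 0.11 (adjusted p = 5.6e-42, and 0.0017 with an estimated correlation). Dihydroflavonol reductase DFR (AT5G42800) had 86.7 ± 26 CPM in Col-0 and 3.66 ± 0.87 in Per-1 there (-4.72 ± 0.20, n = 12). In shoots the anthocyanin mean was -2.06 ± 0.12 and -1.79 ± 0.12 (adjusted p = 4.6e-18 and 3.1e-16, or 0.23 and 0.26 with an estimated correlation), and the first was -1.89 without the shoots of 3 DAS (adjusted p = 1.4e-14). Wounding and jasmonate genes rose in older Per-1 leaves: 16 of 19 were higher and 0 lower at 11 to 15 DAS (16 when adjusted over the list alone). The mean was 2.25 ± 0.13 (adjusted p = 6.6e-29, or 0.27 with an estimated correlation). At 16 to 21 DAS 18 were higher (18 when adjusted over the list alone), by 3.00 ± 0.12 (adjusted p = 4.8e-42, or 0.23 with an estimated correlation). JAZ10 (AT5G13220), a jasmonate repressor, had 0.859 ± 0.36 CPM in Col-0 and 74.2 ± 30 in Per-1 (6.44 ± 0.23, n = 18). Of 20 aliphatic glucosinolate genes 14 were lower and 3 higher in Per-1 shoots of 6 to 8 DAS (-0.56 ± 0.10, adjusted p = 4.9e-06), 17 when adjusted over the list alone. In leaves of 16 to 21 DAS 15 were higher and 4 lower (0.69 ± 0.07, adjusted p = 1.1e-13), 19 when adjusted over the list alone. Both adjusted p-values were 0.91 with an estimated correlation. The myrosinase TGG2 (AT5G25980) was near 0 in Per-1 in every period (707 ± 37 and 2.41 ± 0.57 CPM in leaves of 7 to 10 DAS, -8.17 ± 0.12, n = 12). AOP2 (AT4G03060), which modifies side chains, was higher (27.4 ± 5.6 and 436 ± 140 CPM in leaves of 16 to 21 DAS, 3.99 ± 0.15).

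The flowering repressor FLC (AT5G10140) was higher in Per-1 in all 5 periods, with 2.31 ± 0.23 and 33.6 ± 1.3 CPM in shoots of 3 to 5 DAS (3.86 ± 0.08) and 0.102 ± 0.1 and 52 ± 8.3 in leaves of 16 to 21 DAS (8.96 ± 0.14). It shares 64.9% of its 31-base words with an overlapping gene on the other strand, so part of its counts is uncertain. FT (AT1G65480), the mobile flowering signal, had 2.17 ± 0.73 CPM in Col-0 and 0.0833 ± 0.066 in Per-1 in the oldest leaves (-4.86 ± 0.30). In that period 10 of 17 flowering genes were lower and 4 higher, 14 when adjusted over the list alone. Their mean of -0.07 ± 0.03 and median of -0.25 had the opposite sign to the test (adjusted p = 0.0021, or 0.91 with an estimated correlation), and the mean was 0.11 on log2(TPM + 1). The morning clock genes CCA1 (AT2G46830) and LHY (AT1G01060) were lower in Per-1 in each period, by -0.41 ± 0.11 and -1.71 ± 0.22 in shoots of 3 to 5 DAS. The evening gene PRR5 (AT5G24470) had 0.772 ± 0.46 CPM in Col-0 and 3.87 ± 1.5 in Per-1 leaves of 16 to 21 DAS (2.42 ± 0.22). The clock list as a whole had 6 of 16 genes higher and 4 lower in shoots of 3 to 5 DAS, 11 when adjusted over the list alone, by 0.28 ± 0.05 (adjusted p = 6e-08, or 0.91 with an estimated correlation). It was 0.14 without the shoots of 3 DAS (adjusted p = 0.0012).

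Starch metabolism genes were higher in Per-1, 16 of 22 in shoots of 3 to 5 DAS and 13 in leaves of 16 to 21 DAS (5 lower in each, and 21 and 19 when adjusted over the list alone). The means were 0.24 ± 0.04 and 0.31 ± 0.04 (adjusted p = 1.7e-09 and 3.3e-12, and 0.91 with an estimated correlation), and the first was 0.32 without the shoots of 3 DAS (adjusted p = 1.8e-08). The phosphorylase PHS1 (AT3G29320) rose from 56.8 ± 19 to 186 ± 20 CPM (1.73 ± 0.09, n = 18) and the pyrophosphorylase subunit APL3 (AT4G39210) fell from 58.4 ± 11 to 24.1 ± 5 CPM (-1.29 ± 0.09, n = 18) in the oldest leaves. Auxin and shade genes were lower by -0.26 ± 0.07 in shoots of 3 to 5 DAS and -0.32 ± 0.05 in leaves of 11 to 15 DAS (adjusted p = 1.7e-05 and 2.6e-07, and 0.91 with an estimated correlation). There 12 and 15 of 24 were lower, 3 and 4 higher, and 15 and 19 passed when adjusted over the list alone, and the mean of the shoots was -0.53 without those of 3 DAS. Salicylic acid defence genes were higher by 0.85 ± 0.22 in leaves of 11 to 15 DAS (13 of 21 higher, 1 lower, 14 when adjusted over the list alone, adjusted p = 0.00032, or 0.91 with an estimated correlation). Stomatal lineage genes were lower by -0.33 ± 0.04 at 16 to 21 DAS (10 of 15 lower, 0 higher, 10 when adjusted over the list alone, adjusted p = 7e-20, or 0.91 with an estimated correlation). In the same leaves heat shock genes were lower by -0.99 ± 0.14 (10 of 12 lower, 1 higher, 11 when adjusted over the list alone, adjusted p = 4.3e-10, or 0.91 with an estimated correlation). Cell wall genes were higher by 0.58 ± 0.04 (11 of 19 higher, 2 lower, 13 when adjusted over the list alone, adjusted p = 1.1e-13, or 0.91 with an estimated correlation).

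Root markers differed with age in the shoot samples. In Col-0 at 3 DAS PRP3 stood at 112 ± 27 CPM, against 4.99 ± 3.5 in Per-1 and 1.3 ± 0.53 in F1 (n = 3). At 5 DAS its highest level was 0.0913 ± 0.16 CPM, in Per-1. The root list was lower in Per-1 shoots of 3 to 5 DAS by -0.85 ± 0.17 (1 of 16 genes higher, 2 lower, 3 when adjusted over the list alone, adjusted p = 0.00018, or 0.91 with an estimated correlation), and by -0.29 without the shoots of 3 DAS (adjusted p = 0.2). It was higher by 1.38 ± 0.17 at 6 to 8 DAS (10 higher, 1 lower, 11 when adjusted over the list alone, adjusted p = 5.5e-07, or 0.91 with an estimated correlation). Seed reserve genes moved with it in shoots of 3 to 5 DAS, by -0.26 ± 0.08 (8 of 11 lower, 1 higher, 9 when adjusted over the list alone, adjusted p = 0.00024, or 0.91 with an estimated correlation), and by -0.07 without the shoots of 3 DAS (adjusted p = 0.72). Senescence genes were higher at 11 to 15 DAS by 0.49 ± 0.09 (8 of 17 higher, 3 lower, 11 when adjusted over the list alone, adjusted p = 2.2e-05, or 0.91 with an estimated correlation). Shoot meristem markers (-0.23 ± 0.06, adjusted p = 0.005) and cytosolic ribosome genes (-0.14 ± 0.06, adjusted p = 0.033) were lower in leaves of 7 to 10 DAS, where 1 of 10 and 13 of 24 fell, 1 and 14 when adjusted over the list alone. Both had an adjusted p = 0.91 with an estimated correlation and lost their calls without the leaves of 7 and 8 DAS (adjusted p = 0.81 and 0.18). On those days the clock of the leaves stood at another phase, with CCA1 in Col-0 at 2.98 ± 0.29 CPM at 8 DAS and 157 ± 15 at 9 DAS.

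Some genes were at or near 0 in 1 parent. In shoots of 3 to 5 DAS AT4G07868 averaged 0.00496 CPM in Col-0, 20.9 in F1 and 42.8 in Per-1, and AT1G25098 averaged 89.2, 61.3 and 0. In leaves of 16 to 21 DAS AT1G66860 averaged 0.00343, 66.9 and 85.4 CPM, and the thionin AT1G66100 averaged 112, 61.0 and 0.00304. AT1G25098 and AT4G07868 share 98.1% and 28.1% of their words with other genes, so their counts are uncertain. Across all genes tested, Per-1 was higher in 6444, 6320, 5278, 7063 and 7537 genes and lower in 5925, 5735, 5203, 6693 and 7157 in the 5 periods (edgeR, 20802 genes tested in shoots and 20743 in leaves). Between 3312 and 5970 of these differed at least 1.5-fold, and 52.1% were higher in shoots of 3 to 5 DAS against 35.3% on log2(TPM + 1). Without the shoots of 3 DAS 10824 genes passed in shoots of 3 to 5 DAS, and without the leaves of 7 and 8 DAS 8291 passed in leaves of 7 to 10 DAS.

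**Figure D1:**
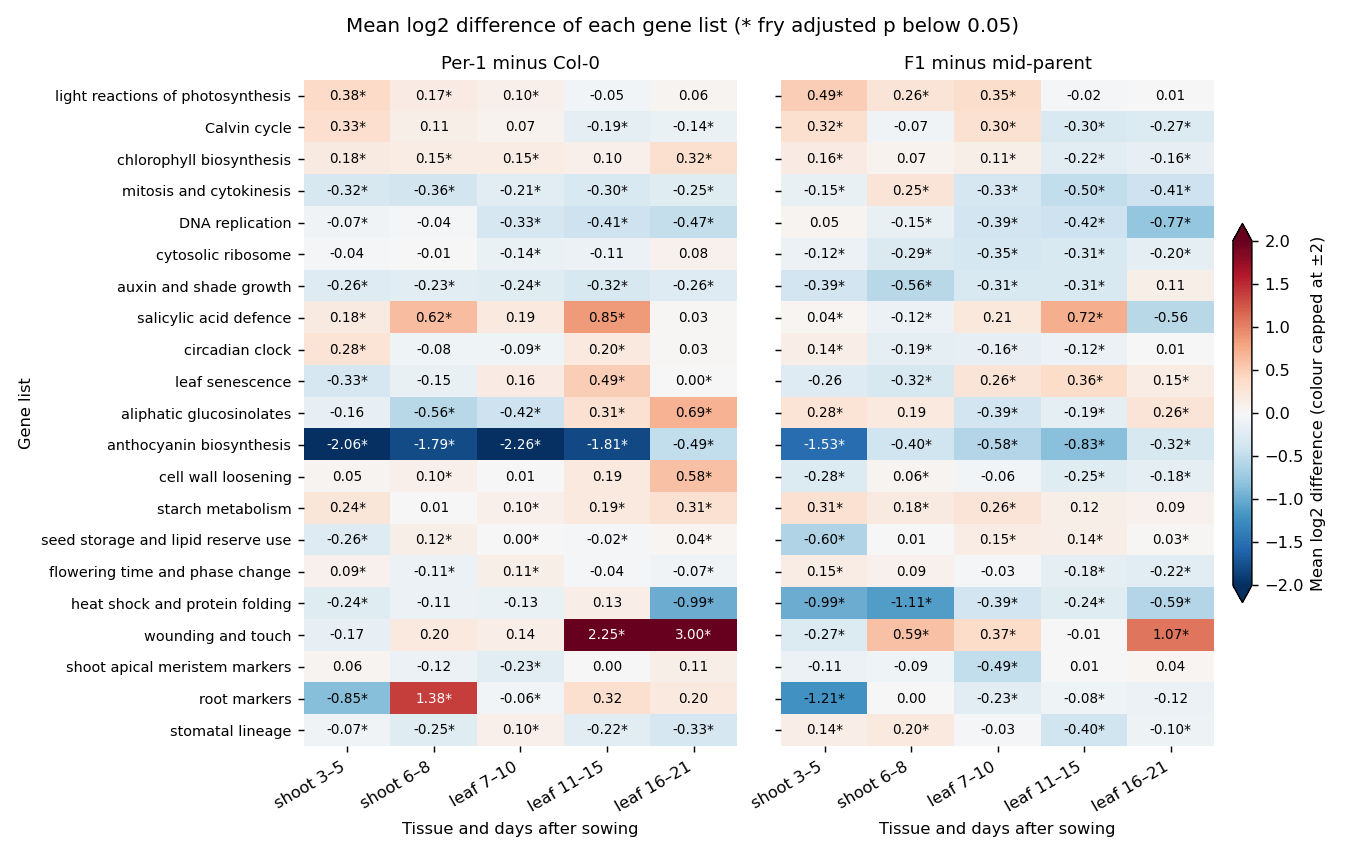
Heat map of the mean log2 difference of 21 gene lists (vertical axis) in 5 periods (horizontal axis), for Per-1 minus Col-0 and for F1 minus the mid-parent, with colours capped at a log2 difference of 2. Wounding genes reach 3.00 and anthocyanin genes -2.26 in the parental comparison.

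The comparison of F1 with the mean of its parents asked where the hybrid departed from an additive level. In F1 shoots of 3 to 5 DAS and leaves of 7 to 10 DAS, photosynthesis genes were above the mid-parent, and from 7 DAS on the leaves had lower levels of mitosis, DNA replication and ribosome genes. None of these list calls passed with an estimated correlation. PSBQ-2 (AT4G05180), of the oxygen-evolving complex, had 717 ± 74 CPM in Col-0, 1320 ± 80 in F1 and 968 ± 70 in Per-1 shoots of 3 to 5 DAS (0.69 ± 0.05 above the mid-parent, n = 9). MCM3 (AT5G46280), of the replicative helicase, had 56.2 ± 3.5, 37.2 ± 3 and 47.7 ± 2.7 CPM in leaves of 7 to 10 DAS (-0.54 ± 0.05, n = 12). Their edgeR adjusted p-values were 1.6e-14 and 2.5e-15.

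All 40 light reaction genes rose above the mid-parent in shoots of 3 to 5 DAS (40 when adjusted over the list alone), by 0.49 ± 0.04 (adjusted p = 2.6e-12, or 0.15 with an estimated correlation), and by 0.36 without the shoots of 3 DAS (adjusted p = 1.1e-07). This mid-parent included the Col-0 shoots with root transcripts, PRP3 standing at 112 ± 27 CPM there and 1.3 ± 0.53 in F1 at 3 DAS. The root list was lower by -1.21 in the same contrast, so root tissue was not excluded as a part of this rise either. The counts were 34 of 40 in shoots of 6 to 8 DAS and 37 in leaves of 7 to 10 DAS with 0 lower, 34 and 37 when adjusted over the list alone. The means were 0.26 ± 0.04 and 0.35 ± 0.04 (adjusted p = 4.2e-06 and 1.5e-14, or 0.43 and 0.12 with an estimated correlation). From 11 DAS they did not depart from the mid-parent as a list. At 11 to 15 DAS 4 were higher and 8 lower at -0.02 ± 0.03 (adjusted p = 0.41), or 0.045 on log2(TPM + 1). At 16 to 21 DAS 15 were higher and 13 lower at 0.01 ± 0.03 (adjusted p = 0.94), or -0.037 with RLE scaling. Calvin cycle genes were above in 18 of 19 in the youngest shoots and in 18 in leaves of 7 to 10 DAS, 19 and 18 when adjusted over the list alone. The means were 0.32 ± 0.04 and 0.30 ± 0.03 (adjusted p = 5.5e-09 and 3.7e-15, or 0.19 and 0.12 with an estimated correlation). Without the shoots of 3 DAS and the leaves of 7 and 8 DAS they were 0.14 and 0.2 (adjusted p = 0.0056 and 2.5e-05). In leaves of 11 to 15 and 16 to 21 DAS 19 and 18 fell below, 19 and 18 when adjusted over the list alone. The means were -0.30 ± 0.03 and -0.27 ± 0.02 (adjusted p = 1.2e-16 and 9.1e-16, or 0.19 and 0.32 with an estimated correlation). The Rubisco small subunit RBCS1A (AT1G67090) had 17800 ± 1700, 24400 ± 1900 and 19800 ± 730 CPM in Col-0, F1 and Per-1 in shoots of 3 to 5 DAS (0.44 ± 0.04) and 27300, 22300 and 24200 CPM in leaves of 11 to 15 DAS (-0.23). Chlorophyll synthesis genes were higher in 14 of 19 in the youngest shoots, by 0.16 ± 0.03 (16 when adjusted over the list alone, adjusted p = 1.5e-05, or 0.38 with an estimated correlation), and by 0.11 without the shoots of 3 DAS (adjusted p = 0.27). In leaves of 11 to 15 DAS 17 fell and 1 rose, 18 when adjusted over the list alone, by -0.22 ± 0.03 (adjusted p = 5.6e-18, or 0.17 with an estimated correlation).

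Mitosis genes fell below the mid-parent in all 3 leaf periods: 28, 26 and 18 of 28 were lower and 0, 0 and 1 higher, 28, 26 and 19 when adjusted over the list alone. The means were -0.33 ± 0.06, -0.50 ± 0.05 and -0.41 ± 0.05 (adjusted p = 5.6e-07, 3.4e-14 and 2e-12, or 0.28, 0.19 and 0.36 with an estimated correlation). In shoots they were lower at 3 to 5 DAS, 12 genes by -0.15 ± 0.04 (13 when adjusted over the list alone, adjusted p = 0.0015, or 0.49 with an estimated correlation), and by -0.05 without the shoots of 3 DAS (adjusted p = 0.42). They were higher at 6 to 8 DAS, 22 genes by 0.25 ± 0.04 (23 when adjusted over the list alone, adjusted p = 9.4e-07, or 0.37 with an estimated correlation). HIK (AT1G18370), a kinesin of the phragmoplast, had 8.36 ± 2, 4.08 ± 0.71 and 6.74 ± 1.7 CPM in Col-0, F1 and Per-1 leaves of 11 to 15 DAS (-0.82 ± 0.09, n = 15). DNA replication genes fell in 24, 23 and 22 of 25 in the leaf periods with 0 higher, 24, 23 and 23 when adjusted over the list alone. The means were -0.39 ± 0.05, -0.42 ± 0.04 and -0.77 ± 0.04 (adjusted p = 4.6e-13, 1.3e-16 and 5.1e-34, or 0.12, 0.17 and 0.094 with an estimated correlation), and the mean at 7 to 10 DAS was -0.58 without the leaves of 7 and 8 DAS. The replicative helicase subunit MCM6 (AT5G44635) had 1.8 ± 0.48, 0.607 ± 0.22 and 1.27 ± 0.39 CPM in the oldest leaves (-1.41 ± 0.14, n = 18). Cytosolic ribosome genes fell in 17, 24, 24, 23 and 19 of 24 in the 5 periods with 0 higher, 19, 24, 24, 23 and 19 when adjusted over the list alone. Their means were -0.12 ± 0.03, -0.29 ± 0.03, -0.35 ± 0.05, -0.31 ± 0.05 and -0.20 ± 0.04 (adjusted p = 0.001, 1.2e-10, 5.1e-09, 1.7e-08 and 4.1e-05, or 0.5, 0.19, 0.19, 0.42 and 0.63 with an estimated correlation). Without the shoots of 3 DAS the ribosome mean of the youngest shoots was -0.06 (adjusted p = 0.19).

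**Figure D2:**
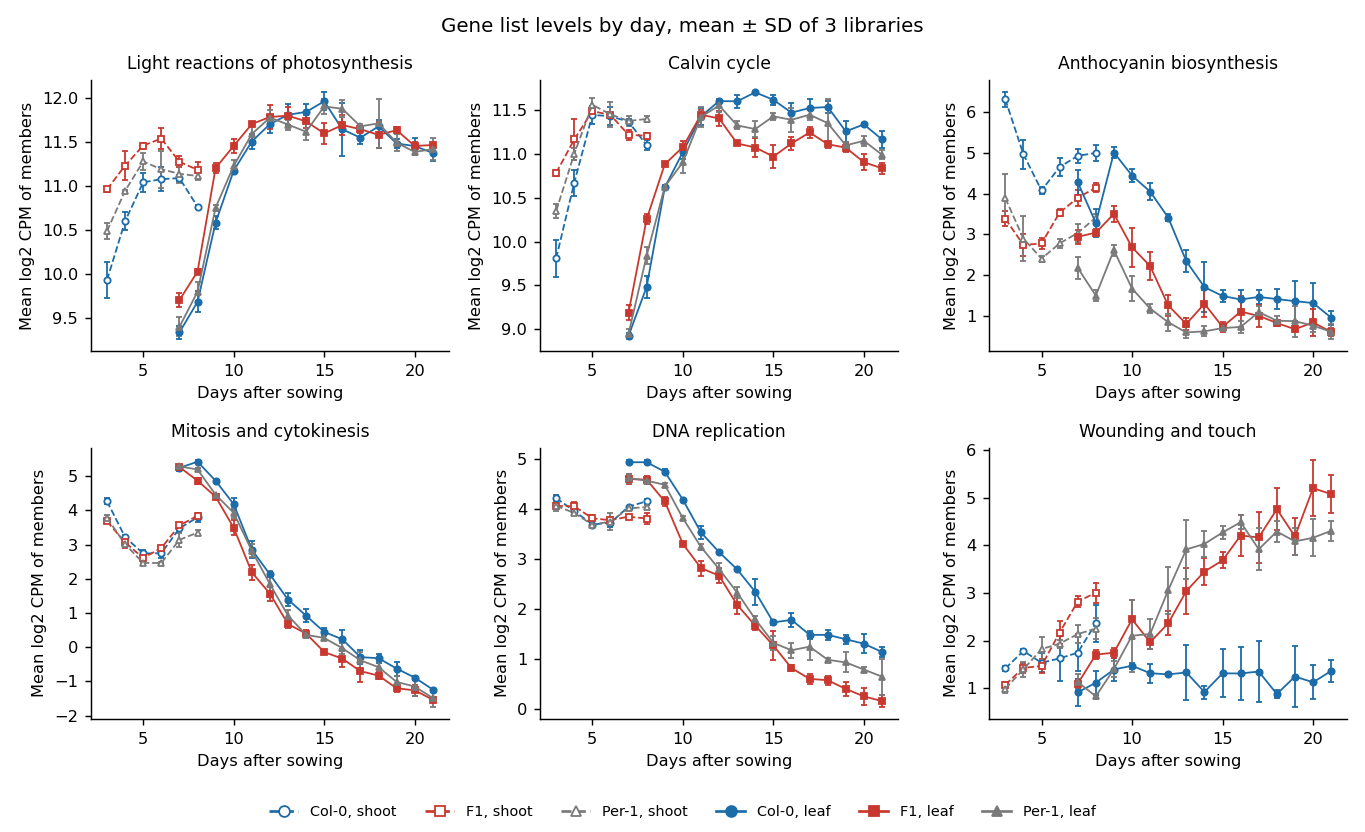
Mean level of 6 gene lists (vertical axes, log2 CPM) by days after sowing (horizontal axes) in shoots and leaves of Col-0, F1 and Per-1, as the mean ± SD of 3 libraries. The mean of the mitosis genes falls (-5.48) from leaves of 7 to 10 DAS to leaves of 16 to 21 DAS.

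Starch, heat shock and flavonoid genes also departed from the mid-parent in F1. Starch genes were higher in 18 of 22 in the youngest shoots and in 18 in leaves of 7 to 10 DAS (3 and 1 lower, 21 and 19 when adjusted over the list alone). The means were 0.31 ± 0.04 and 0.26 ± 0.04 (adjusted p = 8.7e-12 and 9.5e-10, or 0.12 and 0.17 with an estimated correlation), and the first was 0.32 without the shoots of 3 DAS (adjusted p = 1.1e-07). The phosphorylase PHS2 (AT3G46970) had 32.2 ± 8.8, 167 ± 39 and 74.8 ± 21 CPM in Col-0, F1 and Per-1 shoots of 3 to 5 DAS (1.68 ± 0.13, n = 9). Heat shock genes were lower in 9 and 11 of 12 in shoots of 3 to 5 and 6 to 8 DAS (1 higher in each, 10 and 12 when adjusted over the list alone). The means were -0.99 ± 0.12 and -1.11 ± 0.12 (adjusted p = 3.4e-10 and 2.5e-11, and 0.17 with an estimated correlation in both), and the first was -1.28 without the shoots of 3 DAS (adjusted p = 7.2e-09). HSP70 (AT3G12580), a heat-induced chaperone, had 97.8 ± 24, 17.9 ± 3.8 and 61.9 ± 16 CPM at 3 to 5 DAS (-2.01 ± 0.22). Anthocyanin genes were lower in 16 of 17 in the youngest shoots (16 when adjusted over the list alone), by -1.53 ± 0.10 (adjusted p = 2e-16, or 0.094 with an estimated correlation), and by -1.20 without the shoots of 3 DAS (adjusted p = 4.6e-12). Root markers were lower by -1.21 in the same contrast, so root tissue was not excluded as a part of the changes in the youngest shoots. Anthocyanin genes were also lower by -0.83 ± 0.08 in leaves of 11 to 15 DAS (11 lower, 0 higher, 11 when adjusted over the list alone, adjusted p = 5.5e-23, or 0.12 with an estimated correlation). Chalcone synthase TT4 (AT5G13930) had 275 ± 41, 64.7 ± 9.9 and 77.9 ± 7.9 CPM there (-1.68 ± 0.11, n = 15). Auxin and shade genes were lower in shoots of 6 to 8 DAS by -0.56 ± 0.06 (14 of 24 lower, 2 higher, 16 when adjusted over the list alone, adjusted p = 1.5e-11, or 0.17 with an estimated correlation). IAA1 (AT4G14560), an early auxin response gene, had 15.9 ± 2.5, 2.7 ± 0.64 and 5.83 ± 1.3 CPM there (adjusted p = 3.8e-17).

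Seed reserve genes fell below the mid-parent in the youngest shoots, 10 of 11 by -0.60 ± 0.07 (10 when adjusted over the list alone, adjusted p = 1.3e-10, or 0.15 with an estimated correlation), and by -0.43 without the shoots of 3 DAS (adjusted p = 5.4e-06). Isocitrate lyase ICL (AT3G21720), of the glyoxylate cycle that uses seed oil, had 1340 ± 270, 282 ± 49 and 501 ± 260 CPM (-1.78 ± 0.15, n = 9). Root markers were lower in the same shoots by -1.21 ± 0.15 (8 of 16 lower, 0 higher, 8 when adjusted over the list alone, adjusted p = 4.7e-09, or 0.17 with an estimated correlation), PRP3 among them with the Col-0 level of 3 DAS given above, and by -0.86 without the shoots of 3 DAS (adjusted p = 1.6e-05). Wounding genes were higher in leaves of 16 to 21 DAS by 1.07 ± 0.11 (12 of 19 higher, 0 lower, 12 when adjusted over the list alone, adjusted p = 3.1e-19, or 0.19 with an estimated correlation). The lipoxygenase LOX3 (AT1G17420) had 6.73 ± 1.7, 389 ± 200 and 93.4 ± 37 CPM (3.08 ± 0.15, n = 18). Salicylic acid genes were higher at 11 to 15 DAS by 0.72 ± 0.19 (11 of 21 higher, 1 lower, 13 when adjusted over the list alone, adjusted p = 4.6e-05, or 0.46 with an estimated correlation). At 16 to 21 DAS their mean was -0.56 ± 0.18 (adjusted p = 0.074), and the marker PR1 (AT2G14610) averaged 21.3 ± 47, 3.56 and 26.1 CPM. Senescence genes rose by 0.36 ± 0.07 at 11 to 15 DAS (8 of 17 higher, 2 lower, 10 when adjusted over the list alone, adjusted p = 2.9e-05, or 0.42 with an estimated correlation). The senescence regulator NAP (AT1G69490) was below the mid-parent at 16 to 21 DAS, with 89.5 ± 13, 10.1 ± 4.5 and 47.5 ± 27 CPM (-2.81 ± 0.16). Aliphatic glucosinolate genes were below in leaves of 7 to 10 DAS by -0.39 ± 0.07 (3 of 20 higher, 12 lower, 15 when adjusted over the list alone, adjusted p = 5.2e-05, or 0.42 with an estimated correlation). The mean was -0.12 without the leaves of 7 and 8 DAS (adjusted p = 0.65). They were above by 0.26 ± 0.06 at 16 to 21 DAS (14 higher, 2 lower, 17 when adjusted over the list alone, adjusted p = 4.7e-05, or 0.59 with an estimated correlation).

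Stomatal lineage genes were below the mid-parent in leaves of 11 to 15 DAS by -0.40 ± 0.04 (12 of 15 lower, 2 higher, 14 when adjusted over the list alone, adjusted p = 9.1e-16, or 0.19 with an estimated correlation). Cell wall genes were below there by -0.25 ± 0.04 (9 of 19 lower, 4 higher, 13 when adjusted over the list alone, adjusted p = 1.2e-11, or 0.42 with an estimated correlation). Flowering genes were below at 16 to 21 DAS by -0.22 ± 0.02 (8 of 17 lower, 4 higher, 12 when adjusted over the list alone, adjusted p = 3.3e-07, or 0.63 with an estimated correlation). FLC in F1 had 45.7 ± 5.9 CPM there, 0.85 ± 0.16 above the mid-parent (adjusted p = 1.7e-06). Meristem markers were below in leaves of 7 to 10 DAS by -0.49 ± 0.05 (2 of 10 lower, 1 higher, 3 when adjusted over the list alone, adjusted p = 2.6e-12, or 0.16 with an estimated correlation). The mean was -0.03 without the leaves of 7 and 8 DAS (adjusted p = 0.44). CCA1 and LHY were below the mid-parent in each period, LHY by -2.35 ± 0.21 in shoots of 3 to 5 DAS with 250 ± 96, 31.6 ± 15 and 80.9 ± 33 CPM. The clock list in leaves of 11 to 15 DAS had a mean of -0.12 and a negative test (adjusted p = 0.00052, or 0.99 with an estimated correlation), against a positive median of 0.22, with 7 of 16 genes higher, 6 lower and 13 passing when adjusted over the list alone.

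**Figure D3:**
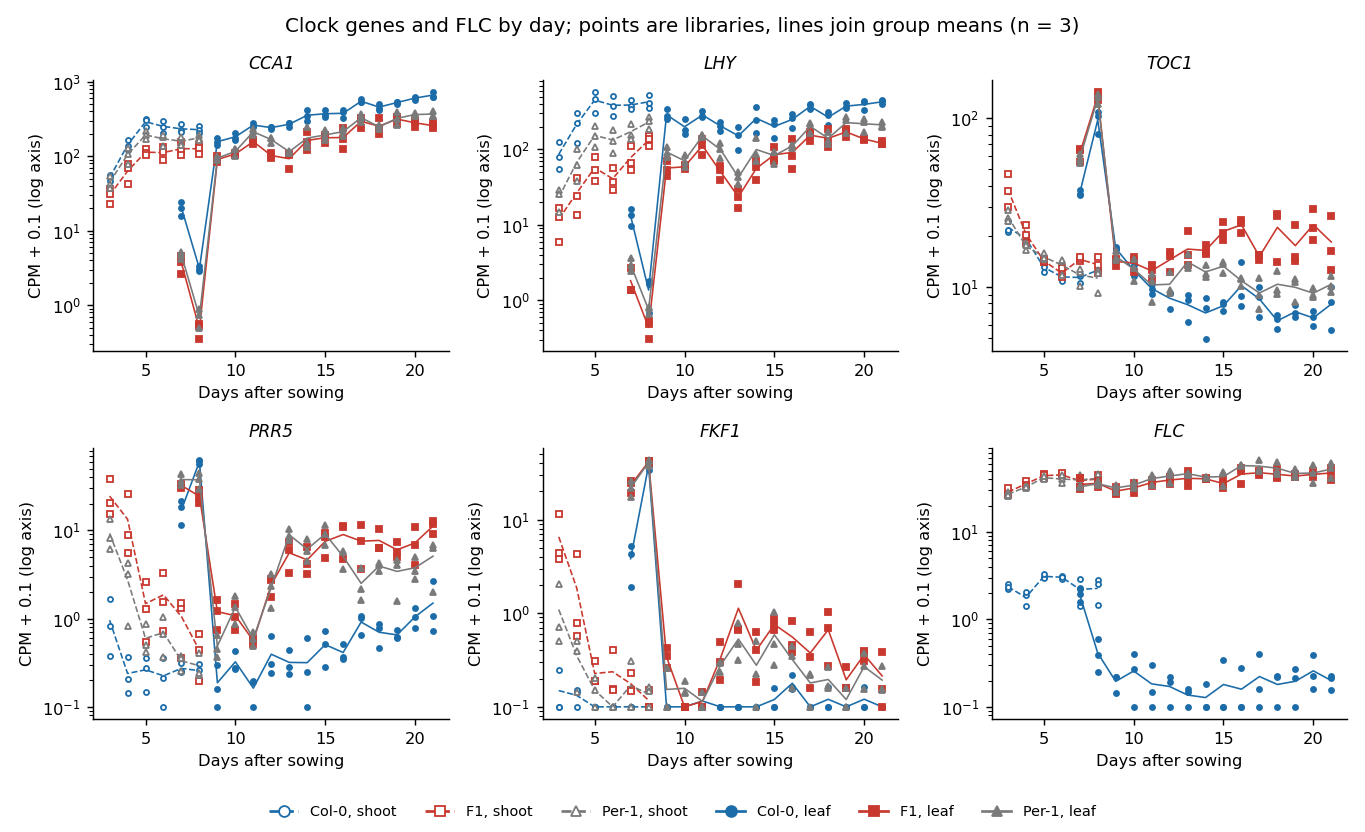
Levels of 6 clock and flowering genes (vertical axes, CPM + 0.1 on a log scale) by days after sowing (horizontal axes) in Col-0, F1 and Per-1, with a point for each library. CCA1 and LHY are lowest in F1 in shoots of 3 to 5 DAS, and FLC in F1 and Per-1 stays above Col-0.

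Among single genes, the epithiospecifier modifier ESM1 (AT3G14210) was above the mid-parent in the youngest shoots (161, 385 and 14.6 CPM, 2.23 ± 0.09, n = 9). The expansin EXPA16 (AT3G55500) was above it in shoots of 6 to 8 DAS (4.01, 46.9 and 8.83 CPM, 2.98 ± 0.13), and AT2G24600, an ankyrin repeat gene, in the oldest leaves (1.98, 64.8 and 7.32 CPM, 3.68 ± 0.20, n = 18). ELIP1 (AT3G22840), an early light-induced protein, was below it in leaves of 7 to 10 DAS (199, 33.4 and 58.7 CPM, -1.79 ± 0.11, n = 12). F1 was above the mid-parent in 4388, 5997, 3646, 5261 and 6231 genes and below it in 4544, 4947, 4820, 6547 and 6603 in the 5 periods. Of these 1832, 2164, 839, 2212 and 3293 departed at least 1.5-fold. The share above it moved under alternatives that changed the model and the scaling together: 49.1% in the youngest shoots against 17.7% on log2(TPM + 1), 43.1% against 27.0% in leaves of 7 to 10 DAS. It was 44.6% against 57.3% at 11 to 15 DAS, and 48.6% against 38.5% with DESeq2 at 16 to 21 DAS. The first F1 library of 15 DAS leaves stood apart from its replicates, with ribosomal RNA gene AT3G41979 at 49000 CPM against 2000 in the other 2. Without it 11502 genes passed at 11 to 15 DAS.

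**Figure D4:**
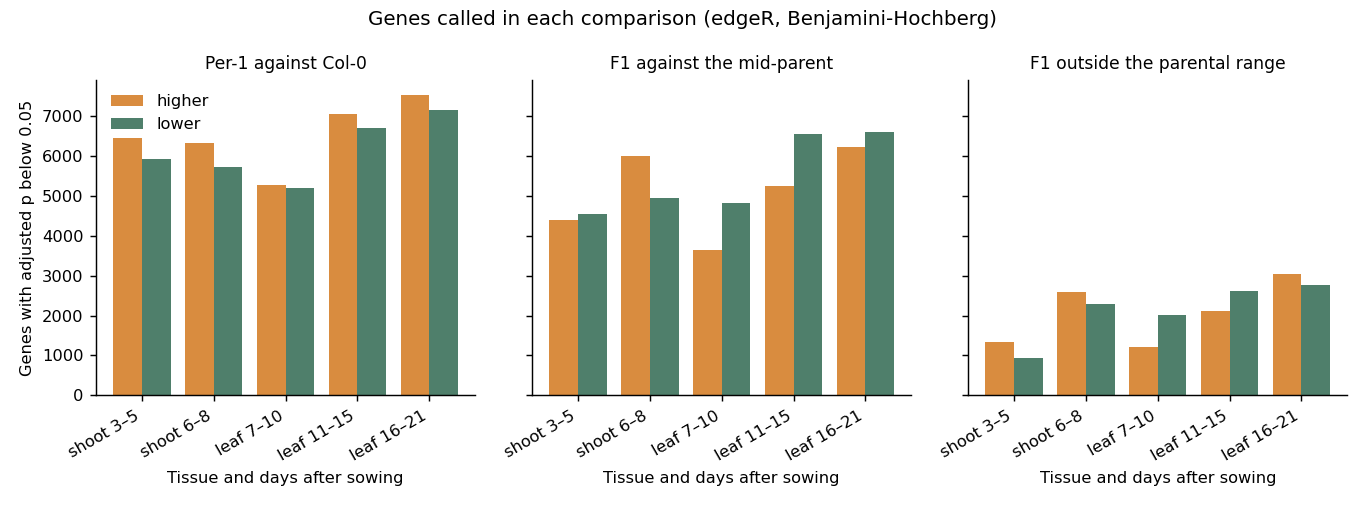
Number of genes (vertical axis) called higher or lower in each period (horizontal axis) for Per-1 against Col-0, F1 against the mid-parent and F1 outside the parental range. In leaves of 16 to 21 DAS the last comparison holds 3039 genes above and 2760 below both parents.

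The comparison of F1 with each parent separately asked which genes left the parental range. In the youngest shoots 37 of 40 light reaction genes and 12 of 19 Calvin cycle genes were above both parents, and in leaves of 7 to 10 DAS 36 and 17. In those leaves 17 of 25 DNA replication, 16 of 28 mitosis and 24 of 24 ribosome genes were below both. In leaves of 11 to 15 DAS 16 of 19 Calvin cycle genes were below both parents. ASN1 (AT3G47340), an asparagine synthetase, had 9.01, 63.2 and 7.43 CPM in Col-0, F1 and Per-1 leaves of 16 to 21 DAS, 3.22 above the nearer parent. ELIP2 (AT4G14690) was below both parents there (29.7, 4.28 and 21.5 CPM, -2.37), and BGLU18 (AT1G52400), a beta-glucosidase, above both in the youngest shoots (7.88, 23.6 and 8.05 CPM, 1.64). HSP90.1 (AT5G52640) was below both there, at 30.5, 7.58 and 24.5 CPM (-1.64). Over all genes, 1345, 2599, 1213, 2107 and 3039 genes were above and 943, 2300, 2008, 2612 and 2760 below both parents in the 5 periods (edgeR, on the larger p of both tests). Leaving out a replicate number gave 1198 to 1637 genes in all in the youngest shoots, against 2288, and 1724 to 2779 in leaves of 7 to 10 DAS, against 3221. Of these 422, 886, 222, 647 and 1391 lay at least 1.5-fold outside. The share above was 58.8% in the youngest shoots, 37.7% in leaves of 7 to 10 DAS and 44.6% at 11 to 15 DAS, against 19.1%, 21.0% and 61.7% on log2(TPM + 1). It was 52.4% at 16 to 21 DAS against 40.3% with DESeq2 and 41.3% with RLE scaling.

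Where the parents differed at least 2-fold, the position of F1 on a scale from 0 at Col-0 to 1 at Per-1 showed which parent it resembled. The median was 0.620, 0.545, 0.532, 0.580 and 0.620 in the 5 periods, over 2471, 2537, 1933, 3058 and 3478 genes, and 26.1%, 19.8%, 12.9%, 22.6% and 27.1% of these genes lay outside 0 to 1. With a 4-fold minimum the medians were lower, at 0.530, 0.501, 0.502, 0.511 and 0.550. With the 2-fold minimum the median of the youngest shoots was 0.542 over 1043 genes higher in Per-1 and 0.717 over 1428 genes lower in Per-1. Col-0 shoots of 3 DAS held root transcripts, such as PRP3, that were low in F1 and Per-1. Root tissue was therefore not excluded as a part of the 0.717. In the youngest shoots the F1 libraries of 3 DAS lay between 0.613 and 0.657 and those of 4 and 5 DAS between 0.565 and 0.578. Each of the 63 F1 libraries lay between 0.504 and 0.717, each Col-0 library between -0.022 and 0.062, and each Per-1 library between 0.919 and 1.031. The values of single libraries rest on a smaller set, the genes still 2-fold apart on the same day with 1 CPM added. Anthocyanin gene DFR in the youngest shoots was near Per-1 (170, 11.7 and 14.5 CPM), whereas TGG2 in the same shoots was above Col-0 (38.5, 61.1 and 0.224 CPM).

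The comparison of late with early periods asked what changed with age. From leaves of 7 to 10 DAS to leaves of 16 to 21 DAS all 28 mitosis genes fell by -5.48 ± 0.04 (28 when adjusted over the list alone, adjusted p = 4.2e-109, and 0.029 with an estimated correlation). HIK went from 96.6 ± 6.2 to 0.633 ± 0.24 CPM (n = 36 and 54). All 25 DNA replication genes and all 24 ribosome genes fell, by -3.45 ± 0.03 and -2.17 ± 0.03 (25 and 24 when adjusted over the list alone, adjusted p = 1.1e-100 and 4.9e-78, or 0.059 and 0.28 with an estimated correlation). Light reaction genes rose in 39 of 40 and Calvin cycle genes in 18 of 19 (39 and 19 when adjusted over the list alone), by 1.21 ± 0.02 and 1.07 ± 0.02 (adjusted p = 1.5e-70 and 1.1e-71, or 0.3 and 0.34 with an estimated correlation). Without the leaves of 7 and 8 DAS these rises were 0.51 and 0.38. The Rubisco activase RCA (AT2G39730) rose from 5940 ± 440 to 18900 ± 1400 CPM (2.02 ± 0.02, or 0.92 without those days). Senescence genes rose in 14 of 17 by 2.21 ± 0.05 (15 when adjusted over the list alone, adjusted p = 2.2e-75, or 0.16 with an estimated correlation). Stomatal lineage genes fell in 12 of 15 by -2.80 ± 0.03 (15 when adjusted over the list alone, adjusted p = 5.7e-91, or 0.14 with an estimated correlation). SPCH (AT5G53210), which starts the lineage, fell from 27 ± 1.6 to 0.339 ± 0.21 CPM. CCA1 also rose, from 64.8 ± 9 to 366 ± 41 CPM (4.32 ± 0.06), and by 1.46 without the leaves of 7 and 8 DAS, which stood at another clock phase. In shoots, from 3 to 5 to 6 to 8 DAS, all 20 glucosinolate genes rose by 1.95 ± 0.06 (20 when adjusted over the list alone, adjusted p = 5.7e-29, or 0.059 with an estimated correlation). Of 11 seed reserve genes 10 fell, by -1.38 ± 0.04 (10 when adjusted over the list alone, adjusted p = 6.9e-25, or 0.13 with an estimated correlation). ICL fell from 707 ± 220 to 3.26 ± 0.78 CPM (n = 27). Light reaction genes rose in 37 of 40 by 0.27 ± 0.03 (37 when adjusted over the list alone, adjusted p = 7.9e-11, or 0.36 with an estimated correlation), and by 0.06 without the shoots of 3 DAS (adjusted p = 0.062). Mitosis genes did not pass at 0.05 ± 0.03 (adjusted p = 0.097), and rose by 0.40 without the shoots of 3 DAS (adjusted p = 8.5e-14).

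With age 7136 genes rose and 6917 fell in shoots, and 9269 rose and 9277 fell in leaves, 3317 and 12824 of them at least 1.5-fold. The share that rose in shoots was 50.8%, against 38.3% on log2(TPM + 1), a scale that moved the median of all leaf genes by -0.183. Whether the parental difference and the F1 deviation themselves changed with age was tested as an interaction. In leaves the F1 deviation of 39 of 40 light reaction genes and 19 of 19 Calvin cycle genes fell, 39 and 19 when adjusted over the list alone, by -0.34 ± 0.05 and -0.57 ± 0.04 (adjusted p = 1.8e-10 and 8.5e-24, or 0.12 and 0.031 with an estimated correlation). Genes whose parental difference changed numbered 4988 in shoots (47.6% upward, against 63.1% on log2(TPM + 1)) and 9971 in leaves. Genes whose F1 deviation changed numbered 6823 in shoots (50.5% upward, against 79.2%) and 9528 in leaves (50.7%, against 69.2%).

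The comparison of the first true leaf with the seedling shoot at 7 and 8 DAS asked how the tissues differed on the same days. In the young leaf all 28 mitosis genes were higher, by 1.69 ± 0.03 (28 when adjusted over the list alone, adjusted p = 1.2e-25, or 0.2 with an estimated correlation). HIK had 149 ± 7.7 CPM against 41 ± 5.4 in the shoot (n = 18). All 25 DNA replication genes were higher by 0.73 ± 0.02 (25 when adjusted over the list alone, adjusted p = 2.6e-22, or 0.2 with an estimated correlation). All 40 light reaction genes and all 19 Calvin cycle genes were lower, by -1.43 ± 0.03 and -1.83 ± 0.02 (40 and 19 when adjusted over the list alone, adjusted p = 3e-25 and 5e-29, or 0.24 and 0.22 with an estimated correlation). RCA stood at 2600 ± 170 against 15000 ± 520 CPM. The clock stood at another phase in these leaves, with CCA1 at 6.02 ± 2.1 against 198 ± 27 CPM and the evening gene FKF1 (AT1G68050) at 32.1 ± 3.8 against 0.0376 ± 0.062 CPM, so tissue and clock phase cannot be separated here. In all 8500 genes were higher and 8691 lower of 20363 tested. The share was 49.4% against 68.0% on log2(TPM + 1), which moved the median of all genes by 0.281.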

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

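The fits without the shoots of 3 DAS and without the leaves of 7 and 8 DAS were tests chosen after the results were seen, and the interactions themselves were planned. Parental differences depended on age in 4988 genes in shoots (2375 upward and 2613 downward) and in 9971 in leaves (5142 and 4829). The F1 deviation depended on age in 6823 genes in shoots (3445 and 3378) and in 9528 in leaves (4831 and 4697). Without the shoots of 3 DAS the shoot counts were 3368 and 4905, and without the leaves of 7 and 8 DAS the leaf counts were 7613 and 7511. Leaving out a replicate number gave 2705 to 3931 and 4325 to 4945 genes in shoots.

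In shoots the advantage of Per-1 over Col-0 shrank with age for the light reactions by -0.21 ± 0.07 (19 of 40 genes fell and 1 rose, 28 when adjusted over the list alone, adjusted p = 0.016, or 0.87 with an estimated correlation). For the Calvin cycle it shrank by -0.22 ± 0.07 (11 of 19 fell, 12 when adjusted over the list alone, adjusted p = 0.0074, or 0.87 with an estimated correlation). Without the shoots of 3 DAS these were -0.11 and -0.1, with an adjusted p = 0.27 in both. The root list turned from lower to higher in Per-1 between the same periods. Root tissue was therefore not excluded as a part of the changes with age in shoots. In leaves the Calvin cycle difference fell by -0.21 ± 0.05 (12 of 19 fell, 13 when adjusted over the list alone, adjusted p = 0.00014, or 0.87 with an estimated correlation) and the chlorophyll synthesis difference rose by 0.17 ± 0.05 (8 rose and 4 fell, 12 when adjusted over the list alone, adjusted p = 0.0023, or 0.87 with an estimated correlation). Without the leaves of 7 and 8 DAS these were -0.12 and 0.11 (adjusted p = 0.068 and 0.062).

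The F1 deviation of the light reactions fell with age in shoots by -0.22 ± 0.06 (28 of 40 fell, 29 when adjusted over the list alone, adjusted p = 0.0011, or 0.22 with an estimated correlation), and by -0.12 without the shoots of 3 DAS (adjusted p = 0.072). That of the Calvin cycle fell in 19 of 19 genes by -0.39 ± 0.06 (19 when adjusted over the list alone, adjusted p = 1.2e-07, or 0.1 with an estimated correlation), and by -0.23 without the shoots of 3 DAS (adjusted p = 0.00081). For chlorophyll synthesis it fell by -0.09 ± 0.04 (7 of 19 fell, 11 when adjusted over the list alone, adjusted p = 0.0023, or 0.24 with an estimated correlation), and by -0.06 without the shoots of 3 DAS (adjusted p = 0.29). Mitosis rose by 0.40 ± 0.06 (25 of 28 rose, 25 when adjusted over the list alone, adjusted p = 6.9e-08, or 0.084 with an estimated correlation), while DNA replication fell by -0.20 ± 0.04 (13 of 25 fell and 1 rose, 16 when adjusted over the list alone, adjusted p = 1.4e-05, or 0.11 with an estimated correlation). Those were 0.28 and -0.27 without the shoots of 3 DAS (adjusted p = 0.00029 and 1.1e-06). In leaves the light reactions fell by -0.34, the Calvin cycle by -0.57 and chlorophyll synthesis by -0.27 ± 0.04 (14 of 19 fell, 14 when adjusted over the list alone, adjusted p = 4.3e-12, or 0.11 with an estimated correlation), and by -0.43, -0.51 and -0.31 without the leaves of 7 and 8 DAS (adjusted p = 3.1e-10, 9.4e-15 and 3.4e-09). DNA replication fell by -0.38 ± 0.06 (16 of 25 fell and 2 rose, 19 when adjusted over the list alone, adjusted p = 3.9e-08, or 0.14 with an estimated correlation), and by -0.22 without the leaves of 7 and 8 DAS (adjusted p = 0.012). That direction turned to 0.025 on log2(TPM + 1).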

How the results depend on the processing

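Some tests were chosen after the results were seen. They include fits without shoots of 3 DAS, leaves of 7 and 8 DAS or the first F1 library of 15 DAS leaves. The alternatives for the tissue comparison of lists were also chosen then. So were those for the age interactions of lists, except camera at a preset correlation, the fits without a replicate number and the replicate block. Of 281 comparisons of a gene count with an alternative, 254 stayed within 1.5-fold of the main count and 27 were weaker. Counts within that window could still fall, as those given above without the shoots of 3 DAS did. Of 2442 comparisons of a list, 1936 kept their call, 460 were weaker, 4 stronger and 42 turned direction. The cause was not tested for values that moved, except for a minimum fold, which removes small differences by construction, and for RLE scaling. That setting kept the model and changed only the scaling, so values that moved under it moved with the scaling.

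With a minimum fold of 1.5, Per-1 and Col-0 differed in 4431, 4492, 3312, 5407 and 5970 genes in the 5 periods from young shoots to old leaves. F1 departed from the mid-parent in 1832, 2164, 839, 2212 and 3293 genes and lay outside the parents in 422, 886, 222, 647 and 1391. With age 3317 genes changed in shoots, the parental difference changed in 1837 and 3780 and the F1 deviation in 1472 and 2366 in shoots and leaves, and the tissues differed in 8772. Leaving out a replicate number gave 2705 to 3931 genes for the change of the parental difference in shoots, 4325 to 4945 for the change of the F1 deviation in shoots, 1198 to 1637 (1339 without replicate 1) for F1 outside the parents in the youngest shoots, and 1724 to 2779 (1849 without replicate 3) in leaves of 7 to 10 DAS. As a replicate block the numbers gave 12544 genes between the parents in the youngest shoots, against 12369. Replicates of the same number correlated between groups with a median r of 0.028 and those of different numbers with -0.018, so the numbers do not pair libraries. List tests passed 338 times with fry, against 342 with the replicate block, 174 with camera at a preset correlation and 3 with camera at an estimated correlation. They include list tests of F1 against each parent that are not given here. Of all genes tested, 40.8% (F1 against the mid-parent, leaves of 7 to 10 DAS) to 89.4% (age in leaves) were called. A fry call alone therefore does not set a list apart from the other genes. For the age interactions camera at an estimated correlation passed 1, against 13 with fry. Since camera compares a list with the other genes, the losses from fry to camera cannot be laid to the correlation alone. The camera settings differed only in the correlation, so the fall from 174 to 3 came with that setting. The position of F1 with a 4-fold minimum was 0.530, 0.501, 0.502, 0.511 and 0.550, and in shoots of 6 to 8 DAS it ran from 0.533 to 0.563 without a replicate number.

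On log2(TPM + 1) these means turned. In the youngest shoots F1 against the mid-parent turned from 0.14 to -0.098 for the clock and from 0.14 to -0.001 for the stomatal lineage, and in shoots of 6 to 8 DAS from -0.12 to 0.040 for salicylic acid defence. Between the parents, seed reserves turned from 0.00 to 0.099 in leaves of 7 to 10 DAS and from -0.02 to 0.22 at 11 to 15 DAS. At 11 to 15 DAS the light reactions turned from -0.05 to 0.006 and the clock from 0.20 to -0.013, and flowering turned from -0.07 to 0.11 at 16 to 21 DAS. The F1 light reactions at 11 to 15 DAS turned from -0.02 to 0.045, and starch with age in leaves from 0.24 to -0.006. Changes of the parental difference turned to 0.029 for mitosis in shoots, and to 0.12 for mitosis and 0.042 for DNA replication in leaves. Changes of the F1 deviation in leaves turned to 0.24 for mitosis and 0.025 for DNA replication. Between leaf and shoot, chlorophyll turned from -0.28 to 0.003, starch from -0.14 to 0.20 and meristem markers from -0.11 to 0.22.

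With members of at least 1 CPM, F1 against the mid-parent was -0.042 for the clock in the youngest shoots and 0.070 for salicylic acid defence at 6 to 8 DAS. Between the parents seed reserves were 0.15 and 0.27 in leaves of 7 to 10 and 11 to 15 DAS, and flowering 0.39 at 16 to 21 DAS. With RLE scaling the F1 means at 16 to 21 DAS were -0.037 for the light reactions and -0.012 for seed reserves. With the replicate block, heat shock with age in leaves was 0.047. Without the shoots of 3 DAS the parental flowering mean of the youngest shoots was -0.027 and the change of the parental DNA replication difference -0.013. Without the leaves of 7 and 8 DAS the parental means of leaves of 7 to 10 DAS were 0.076 for seed reserves and 0.19 for root markers, and the F1 clock mean was 0.067. The F1 means of leaves of 16 to 21 DAS were -0.031 for the light reactions and -0.005 for seed reserves, and the change of the parental mitosis difference was 0.056. Leaving out a replicate number spread salicylic acid defence of F1 in the youngest shoots from -0.032 to 0.095, and the change of the parental difference in shoots from -0.088 to 0.011 for chlorophyll and from -0.024 to 0.073 for DNA replication. Parental seed reserves ran from -0.015 to 0.013 at 7 to 10 DAS and from -0.035 to 0.009 at 11 to 15 DAS. The light reactions at 11 to 15 DAS ran from -0.089 to 0.009 between the parents and from -0.070 to 0.030 for F1, and parental senescence at 16 to 21 DAS from -0.034 to 0.038. Among named genes, DFR in F1 leaves of 7 to 10 DAS turned to 0.27 with the geometric mid-parent, PORB with age in shoots to 0.02 without the shoots of 3 DAS, and RBCS1A with age in leaves to 0.00 on log2(TPM + 1) and -0.37 without the leaves of 7 and 8 DAS.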

Other observations

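The tests of library scaling and of the clock phase as a cause of the photosynthesis pattern were chosen after the results were seen. So were those of the phase in Per-1, of the order of harvest, and of reads lost in Per-1. The list tests of leaf against shoot were added later. The tests of leaves ahead in development, of the phase in F1 and of copies, and the splits, were chosen before. Leaf and shoot of 7 and 8 DAS also differed in auxin and ribosome genes. In the leaf, auxin and shade genes were lower by -1.42 ± 0.05 (20 of 23 lower, 1 higher, 21 when adjusted over the list alone, adjusted p = 4.3e-23, or 0.2 with an estimated correlation), and ribosome genes higher by 0.49 ± 0.03 (24 of 24, 24 when adjusted over the list alone, adjusted p = 6e-16, or 0.36 with an estimated correlation). PORB had 1310 CPM in the leaf and 197 in the shoot. These leaves stood at another clock phase than the shoots, so tissue and phase cannot be separated in these differences either. Between the genotypes, ATSDI1 (AT5G48850), a sulfur deficiency gene, had 1.97, 3.8 and 46.5 CPM in Col-0, F1 and Per-1 leaves of 16 to 21 DAS.

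In F1 leaves of 7 to 10 DAS light reaction genes were above and division genes below the mid-parent, and leaves ahead in development could give both. Placed on the age profile of the parents, F1 leaves of 10 to 15 DAS were ahead by a median of 0.85 days (0.87 ± 0.15, 18 of 18 libraries ahead, 822 genes), against -0.05 for Col-0 and 0.2 for Per-1. The profile came from the parents' own libraries, without the library placed, on genes that did not differ between the parents. The parental leads near 0 are thus partly set by the design. Single libraries reached 1 in Col-0 and 1.1 in Per-1 (SD 0.44 and 0.36). The plan had named the days 9 to 15. A factor per library would move both lists alike, so it cannot give the difference of 0.68 between their deviations. It could still move the level of each list, so scaling was not excluded as a part of either sign. A later clock phase of F1 cannot be told apart. Light reactions were -0.96 in Per-1 leaves of 8 against 9 DAS, but 9 DAS is also a day of growth later. A lead of this size predicted 0.37, -0.52 and -0.32 for light reactions, DNA replication and ribosome at 9 and 10 DAS, where 0.39, -0.58 and -0.46 were found, but it predicted -0.78 for mitosis and 0.34 for the Calvin cycle, where -0.41 and 0.19 were found. At 11 to 15 DAS it predicted -0.46, -0.32, -0.24 and 0.04 for mitosis, DNA replication, ribosome and light reactions, where -0.46, -0.40, -0.30 and -0.02 were found, but 0 for the Calvin cycle, where -0.29 was found.

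CCA1 and LHY were lower in F1 and in Per-1 than in Col-0, which a later clock phase could give. Morning and evening genes were those at least 8-fold higher in leaves of 9 and of 8 DAS, ages also a day of growth apart, picked in Per-1 leaves to test F1 and in F1 leaves to test Per-1. In F1 shoots 73.2% of 71 morning genes were lower and 74% of 50 evening genes higher than in Col-0, as a later phase would give, but by day the shares fell to 57.7% at 3 DAS and 56% at 8 DAS. For Per-1 the lower share was 54.2%, and by day 34.2% (3 DAS) to 78.1% (7 DAS) of morning genes were lower and 45.8% to 58.3% of evening genes higher, so a later phase cannot be told apart there from changes of single clock genes. Both genes were lower than in Col-0 on 21 of 21 combinations of tissue and day, and an order of harvest cannot be told apart because no clock times were given.

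Genes near 0 in a parent could come from lost reads or from copies. Reads lost on the Col-0 sequence lower a gene in Per-1 and raise none, so they cannot give the genes higher in Per-1. Those at least 16-fold higher numbered 77.3% or more of those at least 16-fold lower in each period. Other effects of placing Per-1 reads on the Col-0 sequence were not tested by this count. For the 340 genes at least 16-fold lower in Per-1 leaves of 16 to 21 DAS, lost reads cannot be told apart from low expression, as counts hold no sequence. Of genes at least 16-fold apart, at most 23.9% in a period shared 50% of their words with another gene. The share was at most 25.2% of those higher or of those lower in Per-1. Sharing was rarer among all genes tested, at 4.6% in shoots and 4.8% in leaves. Most genes 16-fold apart thus had no such copy among the annotated genes, and for those that did copies stay open. Words were compared only between annotated genes of the reference. Copies present only in Per-1 were not seen and stay open for all.

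For each gene count only the real grouping, 1 of 100 splits, gave as many genes in a limma fit. The splits for F1 also mixed the parents, and those for the interactions also mixed the days. They therefore cannot test additivity or an interaction apart from the effect of genotype or age. Nor can they show whether the libraries of a group were independent. Between the parents the real and highest other counts were 12823 and 5203, 11647 and 8925, 11991 and 4681, 13668 and 5088, and 14562 and 3329 from young shoots to old leaves. For F1 against the mid-parent they were 9710 and 3105, 10634 and 1427, 10266 and 5697, 11851 and 12, and 12993 and 5362. Outside the parents they were 2545 and 2, 4395 and 2, 4225 and 0, 4410 and 0, and 5469 and 0. With age they were 14392 and 1404 in shoots and 19333 and 11700 in leaves. For the change of the parental difference they were 5517 and 3629, and 11054 and 10367, and for the change of the F1 deviation 7115 and 3, and 10369 and 9815. Leaf against shoot gave 17492 and 12169.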
